A study of Mus musculus with 21 samples.

How the data were processed

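RNA was sequenced from the stromal vascular fraction of mouse inguinal subcutaneous fat, the mixed cells that remain when digested fat is freed of adipocytes, at 7 points of culture with 3 libraries each. Per the labels' protocols, 2 RNA kits were used, the second for small samples, and cDNA was amplified from 15 ng of total RNA before library construction. Which libraries came from which kit is not given in the sources used here. The amplification kit does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. Per the labels, the genome build was GRCm39. The aligner, the counting program, the annotation and the scaling method are not given in the sources used here.

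The authors deposited 1 table of log2 values for 30961 gene models, each with an identifier and a symbol, in 21 columns. In the table, the values of each gene model sum to 0 over the 21 libraries, so that they give relative levels only. The table also holds a pair of floors. The lowest values of a gene model repeat exactly, and the step between the floors is that of 30 to 16, as if 0 reads had been set to 16 and lower values to 30 after each library was multiplied by 1 factor. From these steps the factor of each library and the level of each gene model were recovered. In gene models that reach both floors, 99.92% of 14437 values above the floor and under 200 were whole reads within 0.1 read. The level was recovered for 30291 gene models, and 493 others had 1 value in all libraries. Because the floor follows the factor, it lies at fewer reads in the day 0 libraries (18 to 25) than in most others (25 to 40). The absolute scale rests on reading the floors as 16 and 30. Differences between groups do not depend on it, since they equal those of the deposited values. The recovery was tested on simulated data with 6000 gene models, of which 5986 were resolved and 100.0% of those were right.

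Reads recovered above the floor ranged from 2382246 to 3551484 per library. This leaves out values under the floor and 5 gene models with high values whose level could not be resolved, so the full depth of the libraries is unknown, and no counting interval was computed. A count test was not run because reads under the floor are missing.

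The match between symbols and values was checked with the mouse reference annotation GENCODE M21, which is on GRCm38. It was used for names and for the order and spacing of genes, and no coordinates were converted between builds. Of the identifiers in the table, 28928 were in the reference and 27161 of those had the same symbol. Along each chromosome a hidden Markov model looked for the offset in bases, up to 1.6 Mb in steps of 100, at which the reference exons best separated gene models above the floor from those at the floor. A symbol was kept where the offset was at most 1000 bases with a posterior of at least 0.9. That held for 518 of 16184 protein-coding genes. The 13 protein-coding genes of the mitochondrial genome were kept as well, as an assumption, because that genome was outside the search. The search was tested on simulated data with 4120 genes. It placed 90.3% of them within 500 bases, kept 65.4% of 900 genes without an offset, and kept 589 labels, 0 of them wrongly. Simulated offsets were 0 or drawn from a wide range, so offsets just over 1000 bases were rare, and detection followed the fitted model. The 0 therefore does not measure how many kept symbols are wrong in the real table. A limit of 200 bases was looked at first. The limit of 1000 bases was set with the values of these genes in view. Gene models without a supported symbol were tested and counted, but none is named, and none was renamed from its place.

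Differences were tested with limma 3.58.1 in R 4.3.3, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the other steps. The design set before the data were examined had named a count test, or limma on the log2 of values plus 1 for normalized values. The values were already log2 values with floors, so limma with a trend was run on the recovered log2 levels with no pseudocount. A gene model was tested when its level was above 30 in at least 3 libraries, which left 7768, of which 436 had a supported symbol. All 21 libraries entered 1 fit with the 7 groups as factor. P-values were adjusted by the Benjamini-Hochberg method within each of 10 comparisons, and calls were made at an adjusted p under 0.05. A time course test over days 0 to 28 of primary culture used the F statistic. A gene model was counted as transiently high when it rose by at least 1 log2 unit from day 0 to an intermediate day and fell by at least 1 from there to day 28, both called, whether or not it came back to the day 0 level, and as transiently low in the mirror case. In a simulated comparison of day 3 with day 0 over 7768 gene models, 56 of 100 changes of 1 log2 unit and 88 of 100 changes of 2 log2 units were recovered, with 7 false calls. The simulated values had no floors, and changes were put only into gene models with a mean above 30. These rates therefore do not cover changes to or from a floor.

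Genes were named by a rule fixed before the data were examined, applied to genes with a supported symbol. For each of 7 comparisons it took the 6 largest rises and the 6 largest falls that were called and whose replicates did not overlap. It also took the 8 strongest transient genes in each direction, and members of gene lists. The rule had also asked for a minimum mean level in the higher group, which was not applied. For transient genes it had asked that replicates not overlap, which was not required here. Unnamed models, clones, receptor segments and marked pseudogenes were left out. Of 34 gene lists with 748 genes written beforehand, 26 members in all had a supported symbol and 22 lists had none. Only the list of 13 mitochondrially encoded genes reached the 80% of members required for a test, which was run with limma's camera at a preset correlation of 0.01. From the other lists, single genes are reported for day 28 against day 0, and Ccne2 also for day 3, chosen after its values were seen. None of 28 marker genes of the starting tissue, of heart muscle and of epigenetic enzymes had a supported symbol, so they were not analysed here.

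A fold against a group whose 3 libraries all lie at or under the floor was computed against the floor of 30 and is given as a lower limit. The exception is Mmp10 at day 28, where the higher group also held a library on the floor. Where only 1 or 2 of the 3 libraries lie there, the fitted change is given and is understated. Alternatives were quantile normalization, other filters on low values, the replicate number as a block, a minimum change of 1 log2 unit, fits of the compared groups alone, each library left out in turn, and camera with an estimated correlation or limma's fry for the list. Chosen after the data were seen were a raised zero floor, a fit without the trend, scaling to the median of 3171 gene models above the floor in all libraries, and a fit of the supported genes alone. Quantile normalization was tried on all gene models that vary, which was kept, and on the tested ones.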

Results

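Expression of 30961 gene models was measured in 21 RNA-seq libraries from the stromal vascular fraction of inguinal subcutaneous fat of female C57BL/6J mice. Primary cultures (P0) were sampled on day 0, when the cells were fresh, and on 5 later days (3, 7, 14, 21, 28), and once more after day 28 cells had been passaged and grown for 28 days (P1). Each of the 7 groups had 3 libraries. The labels do not say what a replicate number marks, such as an animal, a pool or a dish, so the p-values measure only the spread between these libraries. The recovered reads above the floor of the deposited values came to 2449437, 2525959 and 3551484 in the day 0 libraries and lay between 2382246 and 3533940 in the others, leaving out 5 high gene models of unresolved level. Between 7387 and 7407 gene models were above the floor in the day 0 libraries, and between 4457 and 4702 in the P1 libraries. The floor lies at a scaled level, which was 18 to 25 reads at day 0 and 32 to 40 reads in P1, so these counts use different read limits. More than 40 reads were reached by 5023 to 5955 gene models at day 0 and 4306 to 4578 in P1. In all, 21104 gene models (68.2%) were above the floor in no library.

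Gene symbols and values went together in only part of the table. On long stretches of most chromosomes, gene models above the floor lined up with the exons of a GRCm38 annotation only after these had been moved along the chromosome by a fixed number of bases. Symbols met the limits for being in place for 518 of 16184 protein-coding genes, 285 on chromosome 4, 119 on chromosome 6, 35 on chromosome 9 and 79 on chromosome 15. More may be in place, since the search kept only 65.4% of simulated genes without an offset. Of the 518 genes, 84.7% were above the floor in at least 1 library, against 43.7% of 15552 genes in blocks with an offset. The blocks were placed by detection itself, so part of this gap could be built in. Every nuclear gene named here lies in those 4 regions, and the counts of called gene models cover the whole table, whose other symbols were not used.

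**Figure D1:**
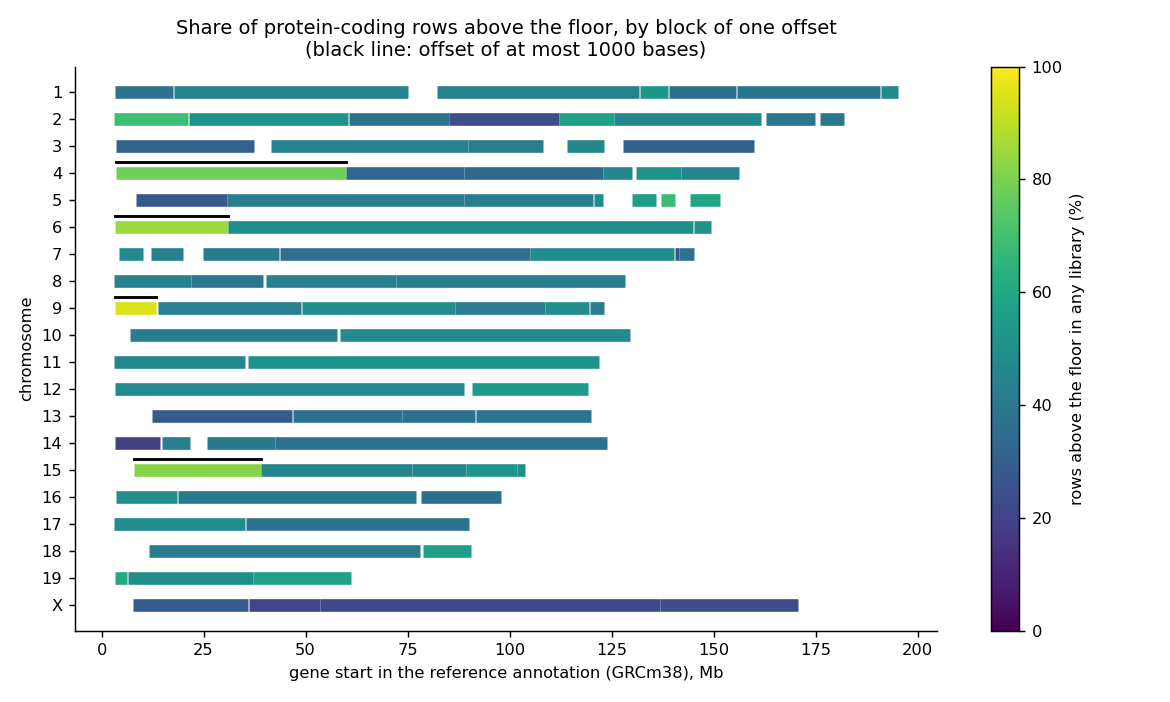
Share of protein-coding gene models above the floor in at least 1 library, in blocks of at least 30 genes that share 1 offset, by chromosome and gene start in the GRCm38 reference annotation (Mb). Black lines mark the blocks with an offset of at most 1000 bases on chromosomes 4, 6, 9 and 15.

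Correlations between replicates across gene models, which are not independent of each other, ranged from 0.937 to 0.963. Days 21 and 28 were not separated in this measure: day 28 replicate 1 correlated with day 28 replicate 3 at 0.937 and with day 21 replicate 1 at 0.954. The first principal component held 47.5% of the variance and the second 17.2%. In the limma F-test over the 6 days of primary culture, 5550 of 7768 tested gene models changed, 368 of them among the 436 with a supported symbol.

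**Figure D2:**
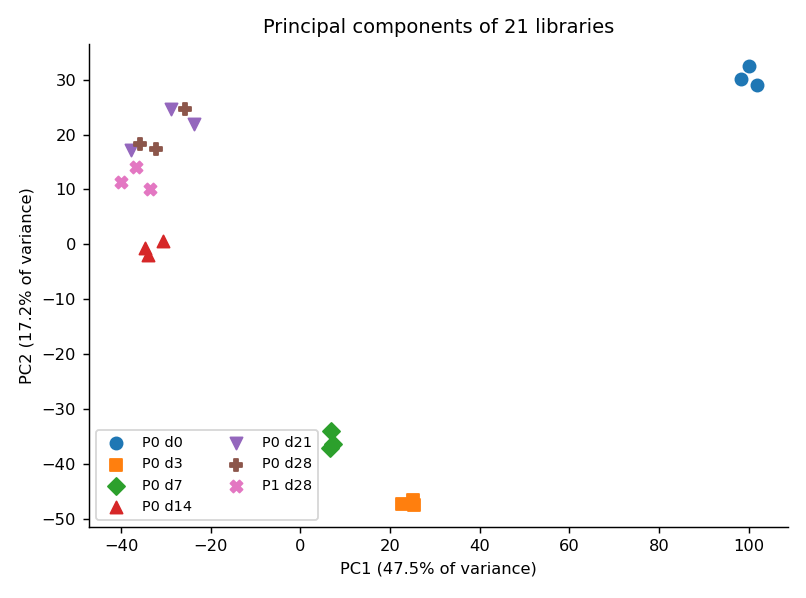
First and second principal components of the 21 libraries, 1 point per library and 1 symbol per group. Day 0 stood apart on PC1, days 3 and 7 on PC2, and days 21 and 28 overlapped.

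Each later day was compared with day 0, which asks how cultured cells differed from the freshly isolated fraction. With limma, 3990 gene models were called at day 3, 842 higher and 3148 lower. At day 7 the call was 4227, with 937 higher and 3290 lower. At day 14 it was 5070, with 730 higher and 4340 lower. At day 21 it was 4604, with 967 higher and 3637 lower, and at day 28 it was 4683, with 1026 higher and 3657 lower. The balance of directions depended on the scaling. After quantile normalization the calls were 1763 higher and 1596 lower at day 3, 1835 and 1682 at day 7, 1968 and 1926 at day 14, 1940 and 1825 at day 21, and 1952 and 1900 at day 28. After scaling to the median gene model they were 1207 higher and 2360 lower at day 3, 1257 and 2524 at day 7, 1304 and 2937 at day 14, 1397 and 2685 at day 21, and 1409 and 2727 at day 28. The median log2 fold change of gene models above the floor in all libraries was -0.26 at day 3, -0.25 at day 7, -0.56 at day 14, -0.34 at day 21 and -0.33 at day 28, and 0.24, 0.27, 0.31, 0.25 and 0.26 after quantile normalization. Changes of single genes below are to be read against these shifts.

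**Figure D3:**
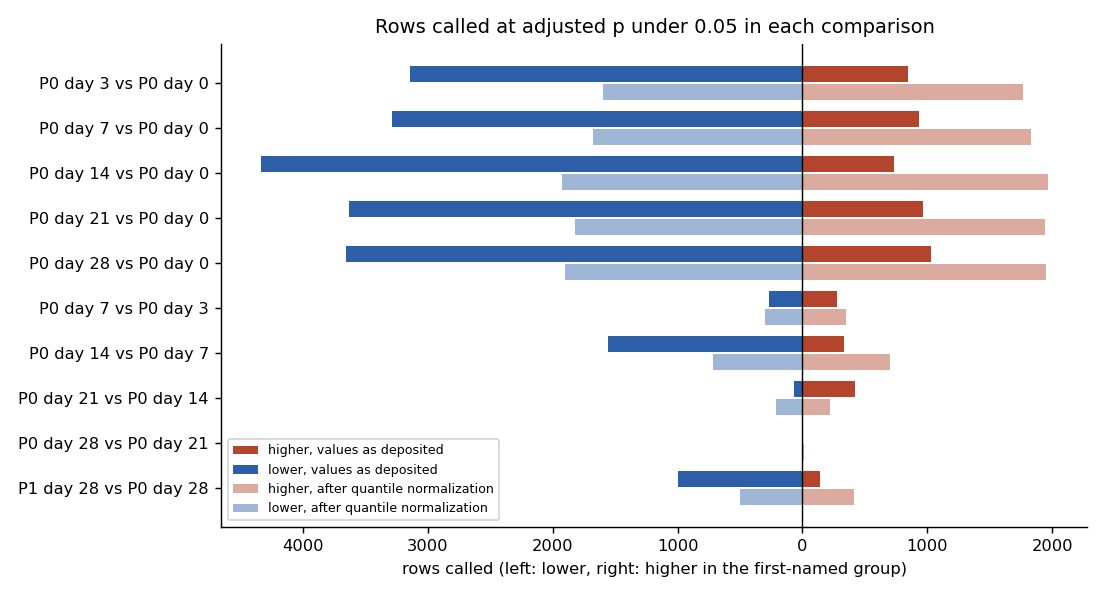
Number of gene models called at an adjusted p under 0.05 in each of the 10 comparisons, higher to the right and lower to the left, for the deposited values (dark bars) and after quantile normalization (pale bars). At day 14 against day 0, 4340 gene models were lower as deposited and 1926 after quantile normalization.

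Among supported symbols at day 3, 102 genes were higher than at day 0 and 165 lower by limma. Glipr2 rose by 3.57 ± 0.09 log2 units (SE, n = 3 per group, limma adjusted p 9.73e-15). Tmeff1 rose by 3.89 ± 0.37 and Melk, a mitotic kinase, by 3.09 ± 0.33. Mmp10, a secreted protease, was at least 17.7-fold higher, Gdf6 at least 13.5-fold and Car9 at least 8.76-fold, since their day 0 libraries lay at or under the floor. The transcription factor gene Klf4 fell by 5.09 ± 0.19 log2 units (limma adjusted p 7.67e-13). Gem fell by 5.96 ± 0.37 and the prolactin receptor gene Prlr fell by 5.94 ± 0.49. The water channel gene Aqp7 was at least 54.1-fold lower, Aqp3 at least 5.64 log2 units lower, and Hepacam2 was at least 16.4-fold lower.

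Among supported symbols at day 28, 114 genes were higher than at day 0 and 182 lower. C1qtnf3 rose by 6.11 ± 0.29 log2 units (SE, n = 3 per group, limma adjusted p 9.52e-12), Svep1 by 5.66 ± 0.22, Glipr2 by 4.62 ± 0.09 and Col28a1 by 4.19 ± 0.40. Atp6v0d2, a proton pump subunit, was at least 78.2-fold higher and Gdf6 at least 27.4-fold. Prlr fell by 10.1 ± 0.49 log2 units (limma adjusted p 1.19e-11) and Coro2a fell by 6.83 ± 0.28. In the lower group, 2 of 3 libraries of C1qtnf3 and of Prlr lay on the floor, so that these changes are understated. The epithelial splicing factor gene Esrp1 was at least 83.2-fold lower, Aqp7 at least 54.1-fold, Cadps2 at least 54.0-fold and Aqp3 at least 5.64 log2 units.

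Single members of the gene lists fixed beforehand were also compared between day 28 and day 0 with limma. The collagen gene Col1a2 rose by 4.11 ± 0.11 log2 units, the protease gene Mmp3 by 4.06 ± 0.36, Wnt2 by 3.06 ± 0.29 and Col15a1 by 1.21 ± 0.30 and the tropomyosin gene Tpm2 was 2.3-fold higher. Mmp13, from the same list as Col1a2 and Mmp3, was not called (log2 fold change 0.76 ± 0.37, adjusted p 0.0859). Nr4a3 fell by 5.51 ± 0.39, with 2 of 3 day 28 libraries on the floor and the other just above it, so that its fall is understated. Klf4 fell by 4.59 ± 0.19 and the chromatin remodeller gene Chd7 fell by 2.42 ± 0.30. Lep, which encodes leptin, was at least 1.78-fold lower. Mmp10 was 1.56-fold higher when set against the floor. That fold is not a lower limit, since a day 28 library of Mmp10 also lay on the floor. Mmp10 was no longer called when the zero floor was raised to the low floor (adjusted p 0.064) or in a fit of the compared groups alone (adjusted p 0.0509). Ccne2 fell by 0.51 ± 0.18 (adjusted p 0.0195), but changed by 0.05 (adjusted p 0.849) after quantile normalization and by -0.17 (adjusted p 0.525) after scaling to the median gene model. Its call was also lost without day 0 replicate 1 (log2 fold change -0.46, adjusted p 0.0602), without day 0 replicate 2 (adjusted p 0.0593) and without day 28 replicate 1 (adjusted p 0.0624). At day 3, a comparison singled out after its values were seen, Ccne2 was higher than at day 0 by 1.36 ± 0.18 (adjusted p 5.4e-06). Dlx5 was not called (adjusted p 0.121).

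**Figure D4:**
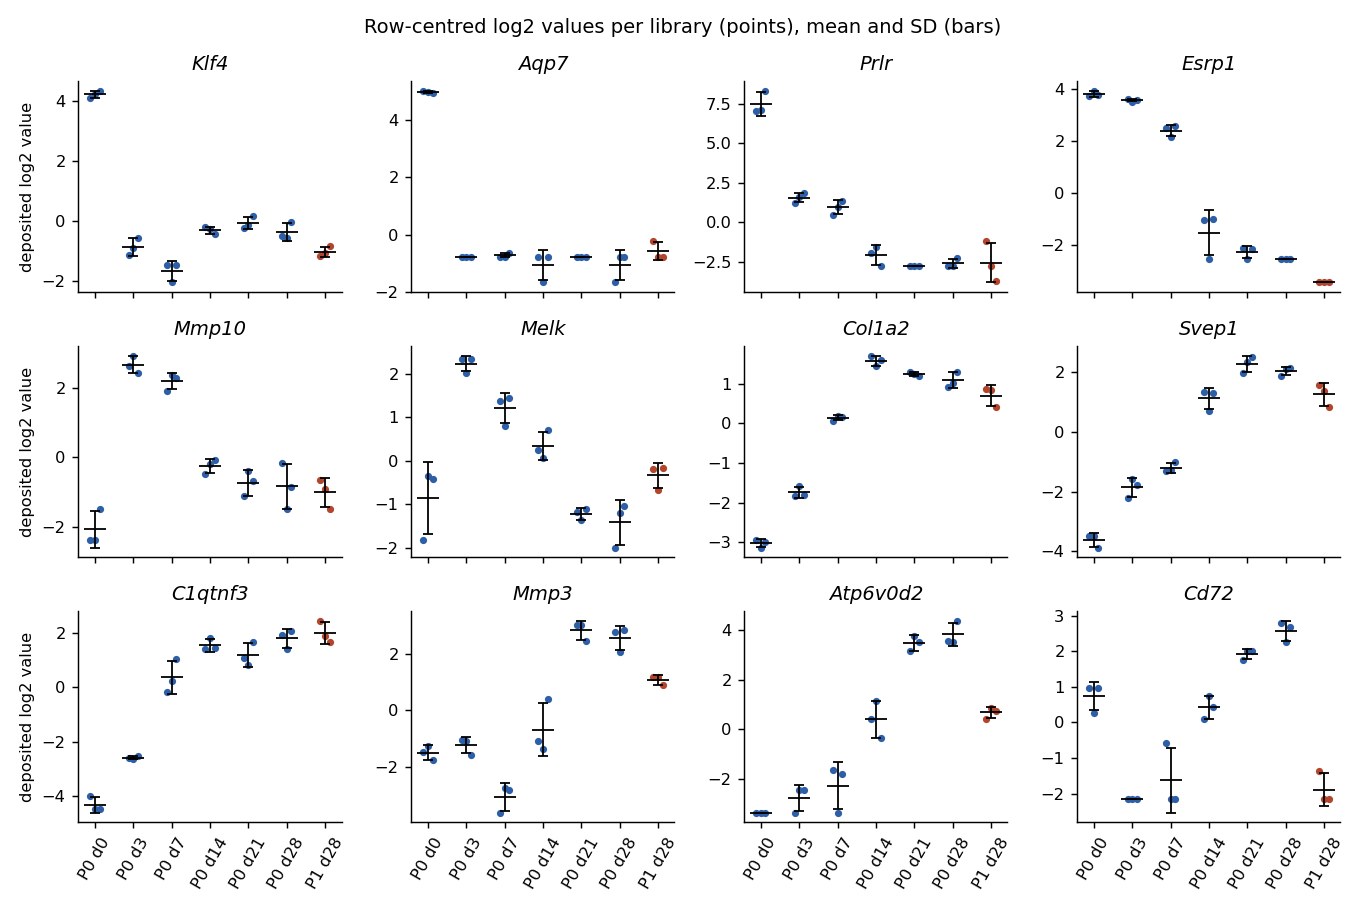
Deposited log2 values, centred on each gene's mean over the 21 libraries, of 12 genes with supported symbols against the 7 groups. Points are libraries (blue P0, red P1), and bars give the mean and SD of 3 libraries. Values repeated at the bottom of a panel, as for Aqp7 or Cd72, lie on a floor.

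Successive days were compared to place changes in time. Between days 3 and 7, limma called 552 gene models, 280 higher and 272 lower. C1qtnf3 rose by 2.95 ± 0.29 log2 units (SE, n = 3 per group, limma adjusted p 5.13e-06), and Rxfp3, Col28a1, Mmp13, Col1a2 and Runx1t1 rose by between 1.81 and 2.05. Col28a1 was not called in a fit of these groups alone (adjusted p 0.0861). At day 3, 2 of 3 libraries of Rxfp3 and 1 of 3 of Col28a1 lay on the floor. Trim14 fell by 1.97 ± 0.27, Mmp3 fell by 1.84 ± 0.36 and Coro2a fell by 1.63 ± 0.28. Cntfr fell by 1.72, Slc44a1 fell by 1.45 and Arhgef39 fell by 1.22. These calls were lost when any of several single libraries was left out. Without one of those libraries, the log2 fold change lay between -1.77 and -1.57 for Cntfr, between -1.53 and -1.06 for Slc44a1 and between -1.32 and -0.93 for Arhgef39. Cntfr had a limma adjusted p of 0.0527 without day 3 replicate 1, 0.0821 without day 3 replicate 3, 0.0637 without day 7 replicate 2 and 0.0635 without day 7 replicate 3. Slc44a1 had 0.0644, 0.0836 and 0.101 without day 3 replicates 1, 2 and 3, and 0.159 without day 7 replicate 3. Arhgef39 had 0.129 and 0.117 without day 3 replicates 1 and 3, and 0.0557 and 0.164 without day 7 replicates 1 and 3.

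Between days 7 and 14, limma called 1889 gene models, 334 higher and 1555 lower. The split was 703 higher and 720 lower after quantile normalization, and 661 higher and 799 lower after scaling to the median gene model. Svep1 rose by 2.33 ± 0.22 log2 units (SE, n = 3 per group, limma adjusted p 7.71e-07), Cped1 by 2.23 ± 0.21, Atp6v0d2 by 2.67 ± 0.42, Mmp3 by 2.38 ± 0.36, Penk by 2.08 ± 0.39 and the lymphocyte and myeloid receptor gene Cd72 by 2.05 ± 0.35. In a fit of these groups alone Atp6v0d2 (adjusted p 0.0505) and Cd72 (adjusted p 0.0589) were not called. Esrp1 fell by 3.94 ± 0.28 (limma adjusted p 3.39e-08), Nipal2 fell by 3.20 ± 0.23, Coro2a fell by 3.08 ± 0.28, Prlr fell by 3.05 ± 0.49 and the epithelial transcription factor gene Grhl2 fell by 2.90 ± 0.24. Cnr1 was at least 8.15-fold lower. In the lower group, 2 of 3 libraries of Cd72 and Coro2a and 1 of 3 of Atp6v0d2, Penk, Esrp1, Prlr and Grhl2 lay on the floor.

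Between days 14 and 21, limma called 492 gene models, 422 higher and 70 lower. The split was 221 higher and 213 lower after quantile normalization, and 258 higher and 174 lower after scaling to the median gene model. Single libraries moved this count. It was 327 without day 14 replicate 2, 316 without day 14 replicate 3, 882 without day 21 replicate 1, 280 without day 21 replicate 2 and 295 without day 21 replicate 3, and it was 151 in a fit of these groups alone. Mmp3 rose by 3.52 ± 0.36 log2 units (SE, n = 3 per group, limma adjusted p 2.4e-05), Col28a1 by 3.23 ± 0.40, Atp6v0d2 by 3.09 ± 0.42, Mmp27 by 2.69 ± 0.31 and Rragd by 2.04 ± 0.29. Wnt16 was at least 2.95-fold higher. Melk fell by 1.56 ± 0.33, Nipal2 fell by 1.22 ± 0.23, Tpm2 fell by 0.67 ± 0.12 and Asns fell by 0.46 ± 0.07. In the fit of these groups alone Mmp3, Atp6v0d2, Wnt16, Nipal2, Tpm2, Cdh6 and Coq3 were not called. Cdh6 fell by 1.32 ± 0.31. Its log2 fold change was -1.06 (limma adjusted p 0.0927) without day 14 replicate 2 and -1.16 (limma adjusted p 0.0928) without day 21 replicate 2. Coq3 fell by 0.50 ± 0.14 (limma adjusted p 0.0479). It was not called without day 14 replicate 1 (0.113), 2 (0.129) or 3 (0.0867), nor without day 21 replicate 1 (0.0806) or 2 (0.23), with log2 fold changes between -0.53 and -0.39. In the lower group, 2 of 3 libraries of Nipal2 and 1 of 3 of Mmp27 and Cdh6 lay on the floor.

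Between days 21 and 28, limma called 8 gene models, 5 higher and 3 lower. The count was 17 without day 21 replicate 1 and 14 without day 21 replicate 3, and it was 15 in a fit of these groups alone. An unadjusted limma p under 0.05 was reached by 415 of 7768 tested gene models, close to the share of 0.05 that no difference at all would give. Klf10 was the gene with a supported symbol among the 8. It fell by 0.73 ± 0.10 log2 units (SE, n = 3 per group, limma adjusted p 0.00313) and was not called in a fit of these groups alone (adjusted p 0.245).

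The P1 cells were compared with P0 cells of day 28 to see what differed after passage. P1 cells had also been in culture for longer, and no unpassaged group of that age was sampled. Passage and added culture time therefore cannot be told apart. With limma, 1141 gene models were called, 143 higher and 998 lower, 752 without P0 day 28 replicate 3, and 527 in a fit of these groups alone, 53 higher and 474 lower. The split was 413 higher and 504 lower after quantile normalization, and 340 higher and 528 lower after scaling to the median gene model. The median log2 fold change of gene models above the floor in all libraries was -0.27, and 0.06 after quantile normalization. Cd72 fell by 4.46 ± 0.35 log2 units (SE, n = 3 per group, limma adjusted p 1.97e-07), Otulinl fell by 4.29 ± 0.28, Atp6v0d2 fell by 3.15 ± 0.42, Tfec fell by 2.95 ± 0.27 and Mmp27 fell by 2.64 ± 0.31. Cavin4 was at least 12.8-fold lower. In the lower group, 2 of 3 libraries of Cd72 and Mmp27 and 1 of 3 of Tfec and Peg10 lay on the floor. Car8 rose by 2.94 ± 0.49 (limma adjusted p 0.000508), Ctnnal1 by 1.78 ± 0.30, Gem by 1.63 ± 0.37, Peg10 by 1.54 ± 0.26, Hrct1 by 1.48 ± 0.29 and Pdk4 by 1.34 ± 0.26. In a fit of these groups alone, Car8, Ctnnal1, Gem and Pdk4 were not called, with adjusted p of 0.101, 0.0631, 0.228 and 0.12.

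Because the series title speaks of transient changes, gene models that rose or fell by at least 1 log2 unit and then moved back by at least 1 by day 28 were counted. The rule does not ask for a return to the day 0 level. Of the tested gene models, 203 were transiently high and 292 transiently low, 25 and 28 of them with a supported symbol. After quantile normalization these counts were 284 and 179. Melk rose by 3.09 ± 0.33 log2 units from day 0 to day 3 and fell by 3.65 ± 0.33 from there to day 28 (SE, n = 3 per group, limma adjusted p 6.41e-07 and 1.6e-07). Smc2 rose by 2.05 ± 0.26 and fell by 2.35 ± 0.26, and Rad54b rose by 2.22 ± 0.42 and fell by 2.58 ± 0.42 over the same days. Mmp10 was at least 17.7-fold higher at day 3 than at day 0 and then fell by 3.50 ± 0.32 to day 28. Cdh10 and Faxc were also high at day 3, and Cdh6 and Cnr1 at day 7. Of the transiently low genes, Cd72 was at least 7.42-fold lower at day 3 than at day 0 and rose by at least 4.73 log2 units to day 28 (limma adjusted p 9.92e-09). Abca1 fell by 2.27 ± 0.17 and then rose by 3.66 ± 0.17, and Col28a1 fell by 2.11 ± 0.40 and then rose by 6.30 ± 0.40. Cd72, Abca1 and Col28a1 ended above their day 0 level. Osr2, Thsd7a and Casp4 were also low at day 3. At their low day, 2 of 3 libraries of Osr2 and 1 of 3 of Col28a1 and Penk lay on the floor, as did 1 of 3 day 0 libraries of Faxc and Cnr1 and 1 of 3 day 28 libraries of Rad54b, Mmp10 and Faxc, so that these changes are understated. Penk was low at day 7, and Trim14, at least 30.6-fold lower than at day 0, was low at day 14.

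The 13 mitochondrially encoded genes were tested as a list. Their median log2 fold change against day 0 was -0.54 at day 3, -0.66 at day 7, -1.12 at day 14, -0.69 at day 21 and -0.85 at day 28. Scaling to the median gene model gave -0.28, -0.41, -0.57, -0.34 and -0.51, with 5, 7, 12, 8 and 12 genes called lower and 0 higher. After quantile normalization, which also moved up the median of gene models above the floor in all libraries, the list's medians were -0.01, -0.03, -0.33, 0.01 and -0.03, so that only day 21 changed sign, and 4, 5, 6, 4 and 5 genes were called lower against 0, 1, 0, 1 and 0 higher. As deposited, limma called 9, 11, 13, 13 and 13 of the genes lower, and 11, 11, 13, 13 and 13 adjusted over the list alone. Between successive days the medians were -0.01, -0.52, 0.43 and -0.19, and after passage the median was -0.58 with 7 genes called lower. Scaling to the median gene model gave -0.03, -0.22, 0.24 and -0.2, and -0.29 after passage with 3 genes called lower and 1 higher. Quantile normalization gave -0.04, -0.15, 0.2 and -0.04, and -0.27 after passage with 6 called lower and 1 higher. Camera at its preset correlation called the list in 8 of 10 comparisons, 7 lower and 1 higher. These included day 21 against 14 and day 28 against 21, where limma called 0 of the 13 genes over all tested gene models. Day 3 against day 0, with 9 genes called, was not among them. Camera called the list in 0 of 10 with the correlation estimated from the data, 0.863, where the smallest unadjusted p was 0.221. At the preset correlation it was called in 1 after quantile normalization, 1 with the stricter filter and 3 after scaling to the median gene model. Camera's call count was 5 without day 0 replicate 2, 5 without day 0 replicate 3, 4 without day 14 replicate 1 and 5 without day 14 replicate 2. Fry, which tests the list against no change and not against the other gene models, called it in 7. At day 28 against day 0, mt-Atp8 fell by 1.40 ± 0.11 log2 units (SE, n = 3 per group, limma adjusted p 8.84e-09), mt-Atp6 fell by 1.32 ± 0.12, mt-Nd3 fell by 1.17 ± 0.20 and mt-Cytb fell by 1.07 ± 0.17, the last not called after quantile normalization (adjusted p 0.118). Nuclear copies of mitochondrial sequence, neighbouring proteases of the Mmp family and Casp1 and Casp4 resemble each other in sequence, and how the authors' counting split such reads is not given in the sources used here.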

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

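Chosen after the data were seen were the raised zero floor, the fit without the trend, scaling to the median gene model and the fit of supported genes alone. Upper-quartile factors, DESeq2 and limma-voom, which need counts, and a pseudocount of 0.1, which values already logged with a floor cannot take, were not run. Of 103 named gene and comparison pairs past the threshold, 82 kept their call and direction under each alternative counted for single genes, and 21 lost the call in at least 1. The minimum change of 1 log2 unit and the fit of supported genes alone were not counted here. The stricter filter was counted only for genes that passed it. Of 1438 alternative values 1387 stayed past the threshold in the same direction, 50 did not pass, and 1 reversed: Ccne2 at day 28 against day 0, at 0.05 after quantile normalization. Of the 50, 18 came from fits of the compared groups alone, 22 from leaving out a library and 6 from no filter.

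Counts of calls follow the comparisons day 3, 7, 14, 21 and 28 against day 0, day 7 against 3, 14 against 7, 21 against 14, 28 against 21, and P1 against P0 at day 28. With the stricter filter, which tests fewer gene models (3648), the first 5 counts were 2142, 2270, 2653, 2454 and 2502, the time course 3001 and the transiently high 115. With no filter, day 21 against 14 gave 309. With a change of at least 1 log2 unit also required, which can only remove calls, the counts that moved by over 1.5 times were 2439, 2639, 3055 and 3072 at days 3, 7, 21 and 28 against day 0, then 265, 783, 226, 4 and 478 in the last 5. With supported genes alone, fewer by construction, the 10 counts were 273, 299, 306, 288, 301, 56, 190, 62, 4 and 194, the time course 371, and the transiently high and low 26 and 30. Fits of the compared groups alone, with fewer libraries, gave 151 for day 21 against 14, 15 for day 28 against 21 and 527 for P1. Quantile normalization gave 14 for day 28 against 21 and 179 for the transiently low. For the counts with no filter or another normalization the cause was not tested.

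Leaving out 1 library in turn gave 3623 to 3813, 3891 to 3999, 4666 to 4858, 4201 to 4517 and 4319 to 4547 against day 0. The successive comparisons gave 404 to 466, 1377 to 1657, 280 to 882 and 8 to 17, and P1 gave 752 to 1073. The time course gave 5249 to 5580, and the transiently high and low 194 to 214 and 232 to 311. Day 21 against 14 moved by over 1.5 times without day 14 replicate 2 (327) or 3 (316), or day 21 replicate 1 (882), 2 (280) or 3 (295). Day 28 against 21 did so without day 21 replicate 1 (17) or 3 (14), and P1 without P0 day 28 replicate 3 (752). The mitochondrial list was called in 4 to 9 comparisons, with 5 without day 0 replicate 2 or 3 or day 14 replicate 2, and 4 without day 14 replicate 1. It was called in 0 with camera's estimated correlation, 1 after quantile normalization, 1 with the stricter filter and 3 after scaling to the median gene model, against 8 as reported. Fry called it in 7, but tests the list against no change and not against the other gene models.

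The replicate number as a block gave 445 for day 21 against 14, 7 for day 28 against 21 and 1079 for P1, and no count moved by over 1.5 times. Deviations of same-numbered libraries from their group means had correlations from -0.118 to 0.12, with 5 of 63 pairs over 0.1, and 7 of 21 libraries correlated best with their own number. This is a hint from the data that the numbers pair nothing, and the design does not say.

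The depth under the floor limits low genes: a gene whose level stays under 30 cannot be followed, and changes from or to the floor are understated.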

Other observations

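Chosen after the result was seen were the tests of offset blocks, of too little sequencing (with held-out families), of reads taken by a few gene models, of the scale against day 0 and of the scale of the passaged libraries. The held-out genes of the last tests were picked by name before their fold changes were computed, but part of their variation over the groups had been in view.

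Genes that every cell uses lay at the floor in most of the table. Of 391 genes of ubiquitous families in blocks with an offset, 161 (41.2%) were above the floor in at least 1 library, against 16 of 17 (94.1%) where symbols were in place. Since the blocks were placed by detection itself, part of this gap could be built in. The search was therefore repeated with these families held out. In blocks placed without them, 15 of 16 (93.8%) were above the floor where symbols were in place and 161 of 391 (41.2%) elsewhere, a gap of 52.6 percentage points. Too little sequencing would lower both alike, so this argues against it. Reads taken by a few gene models would also lower both alike, and within the day 0 libraries the gap was 57.4 percentage points (93.8% against 36.3%), which argues against that too. The limit of 1000 bases for symbols in place was set with detection in view. A candidate explanation is that reads were placed on 1 genome build and counted on gene models of another. One offset per block raised the log-likelihood per gene by 0.144 over no offset, while 10 tables with detection rotated along the chromosome gave -0.032 to -0.022. The chances of detection were fitted to the real table and reused for the rotated ones, whose no-offset model was fitted anew. That favours the real table, so part of this difference could be built in. Neighbouring gene models whose moved exons fall on the same gene had a median correlation of 0.71 (88 pairs), short of the 0.8 set beforehand, against 0.3 for 721 pairs on different genes, so that test left the explanation open. Which of reads and models were on which build is not settled by these values. No biological explanation was tested.

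Against day 0 more gene models were lower than higher. A scale set by a few highly expressed genes could give this. The factors were 1.6422, 1.6697 and 1.2219 in the day 0 libraries and 0.9127, 0.7688 and 1.0774 at day 28. The deposited scale therefore raised the day 0 libraries more. The 10 highest gene models held 14.0% to 14.8% of recovered reads at day 0 and a lower share in each day 28 library. Recovered reads leave out 5 high gene models of unresolved level, so this share does not decide the question. At day 28, after scaling to the median gene model above the floor in all libraries, there were 1750 lower against 790 higher calls of at least 1 log2 unit, or 2.22 per higher call. That reference leaves out gene models that fell to the floor, so part of the excess could be built in. With all tested gene models as reference there were 1454 against 969, and 1419 against 1129 (1.26 per higher call) when values on the floor were moved along. The values do not settle whether the scale is the whole source. Quantile normalization forces equal distributions and says nothing on this. Loss of transcripts found in the fresh fraction only was tested by the share of lower calls with all 3 day 28 libraries at or under the floor. It was 34%, above the 20.4% of the mirror case but under the 50% set beforehand. The floor lay at 18 to 25 reads in the day 0 libraries and at 28 to 39 at day 28. Part of the gap between these shares could therefore be built in. Loss of such transcripts stays open, as does a change within the cells, which was not tested.

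After passage and the added time in culture, Cd72, Tfec, Atp6v0d2 and Otulinl were lower. The scale of the P1 libraries does not explain it, since after scaling to the median gene model the smallest fall among 7 genes, these and the held-out ones, was still -0.89. Fewer white blood cells may be the source. The held-out genes Lyn (-1.53), Casp1 (-1.71) and Mmp12 (-1.18) had a median log2 fold change of -1.53, against -0.22 for all tested gene models, with limma adjusted p of 1.27e-06, 7.77e-05 and 0.00194. This was found and tested on the same libraries. From day 3 to day 28 of primary culture, Lyn, Casp1 and Mmp12 rose by 1.1, 1.61 and 2.73, all called. At day 28 their log2 fold changes against day 0 were 0.31, 1.08 and 2.58. Whether these genes follow the number of white blood cells in culture was not tested. The most abundant marker genes of these cells had no supported symbol and were not analysed here, other cells also express the held-out genes, and lower expression per cell was not tested.

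Melk, Rad54b and Smc2 were high at day 3, which could come from more dividing cells. The held-out genes Fancg, Mms22l, Kif24, Orc3, Rpa3 and Nbn gave no clear answer. Their median log2 fold change at day 3 against day 0 was -0.22, above the -0.42 of all tested gene models but by less than the 0.5 set beforehand. Mms22l rose by 0.96 (limma adjusted p 0.00639) and Nbn fell by 0.53 (limma adjusted p 0.00229). From day 3 to day 28 their median was -0.42: Mms22l fell by 1.39, Kif24 fell by 1.21 and Rpa3 fell by 0.60, all called, Orc3 rose by 0.52, also called, and Fancg and Nbn were not called. Ccne2, the supported member of the proliferation list written beforehand, rose by 1.36 to day 3 (limma adjusted p 5.4e-06), and 1 gene does not decide between more dividing cells and a change of single genes.

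Other splits of the same libraries were counted. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Only 1 of 10, the real one, gave as many calls at day 3 against day 0 (3990, highest other 4), day 7 (4227, highest other 4), day 14 (5070, highest other 1), day 21 (4604, highest other 2) and day 28 (4683, highest other 3). The same held for day 7 against 3 (552, highest other 6), 14 against 7 (1889, highest other 1), 21 against 14 (492, highest other 4) and P1 against P0 (1141, highest other 2). For day 28 against 21, 3 of 10 splits gave at least the 8 calls of the real one. The highest other, 82, set day 21 replicate 1 with day 28 replicates 1 and 2 against the rest, which points to a structure apart from the day. Those libraries also had lower factors (0.833, 0.9127 and 0.7688, against 0.9832 to 1.0774). They had fewer gene models above the floor (4695 to 5069, against 5389 to 5723). Whether this split lies in the samples or in the scaling and floor was not tested. For the time course, 1 of 100 groupings of the 18 P0 libraries, the real one, gave 5550 (highest other 2856). The real grouping was also the only one to give as many transiently high (203, highest other 9, 1 of 100) and low (292, highest other 4, 1 of 100). These groupings argue against no difference at all between the days. They cannot tell a transient change from a lasting one, since shuffled days move real day differences into the spread.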
